A study of Bos taurus with 12 samples.

How the data were processed

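Endometrial biopsies of 12 samples, 3 in each of 4 classes of progesterone concentration on day 4 of the estrous cycle, were sequenced. Per the labels' protocols, RNA was extracted with Trizol and treated with DNase, messenger RNA was captured with oligo-dT, libraries were made with a stranded TruSeq kit, and all 12 were pooled in equal amounts and sequenced as paired reads on 1 instrument. A pool of all libraries leaves no sequencing batch that the labels would separate. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.32 and the genome builds UMD3.1 and bosTau8. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. Because the strand setting is unknown, reads of overlapping genes could not be separated here.

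The authors deposited raw counts, that is, whole numbers of reads per gene symbol, not scaled and not pooled over replicates, in 1 column per sample, and each column carries the title of its sample. The table held 13930 gene symbols, of which 1378 had a count of 0 in every library. The table names 806 microRNA genes, which an mRNA library hardly measures, and 15 of them had enough counts to be tested. Total counts per library ran from 3772564 to 8379489. The total sets the counting precision, and thinning every library to the smallest total was among the alternatives. Of the symbols, 13492 matched the gene table of assembly ARS-UCD2.0 by name and 345 by synonym, and 93 did not match. That table was used for names and for which genes overlap, and no coordinates are given, since the builds differ. Of the 63 genes named by rule, 15 overlap another gene of that table and 2, MYL4 and PILRA, overlap a gene that was tested.

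From the counts, edgeR 4.0.16 in R 4.3.3 was used as the main test. Genes were kept by filterByExpr with the class as group and a count minimum of 10, which left 10959 genes, and the library sizes were scaled by the TMM method (factors 0.728 to 1.11). A quasi-likelihood model of the 4 class means was fitted to all 12 libraries at once, so that every comparison shared 1 estimate of the spread with 8 residual degrees of freedom, and the common dispersion was 0.194, a biological coefficient of variation of 44.0%. The comparisons were the 6 pairs of classes, a joint test of the 4 classes, and a slope on the class rank from 1 to 4. The rank was used because the labels give bounds and the bound of the low class has another unit. P-values were adjusted by Benjamini and Hochberg over the tested genes, with a threshold of 0.05, and fold changes are log2 values of the first class over the second with their standard errors. CPM are counts scaled in the usual way to library size, here after TMM scaling, and SD is the standard deviation over the 3 libraries of a class.

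Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 23 lists, 22 had at least 5 tested members. The list of blood and erythroid markers had 3 and was not tested (median log2 fold change 1.36 for very high against very low). The lists covered steroid receptors and partners, progesterone-associated and estrogen-associated endometrial genes, the cell cycle, interferon-stimulated genes, the prostaglandin and oxytocin pathway, the IGF and growth factor axis, glucose and amino acid transporters, extracellular matrix, lipid metabolism, implantation regulators (WNT and HOX genes), inflammation, markers of T and NK, B and plasma, macrophage and dendritic, neutrophil, epithelial, ciliated, stromal, smooth muscle and endothelial cells, and immediate early and heat shock genes. Some genes, such as OXTR, stand in more than 1 list. The score of a list is the mean log2 CPM of its tested members in a library. In 30 of 154 tests of a list the median, the mean and camera's direction differed in sign, and 4 of those tests passed at the preset correlation. They are named where they are reported.

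The genes named in the text followed a rule. In each of 4 main comparisons it took PGR, ESR1 and OXTR, then the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between classes, and up to 3 members of each list with the smallest p among those past the threshold. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were named as not past it. For the trend it took the 6 smallest p per direction and for the joint test the 6 smallest p. Genes known only by a locus number were not named. Classes, tests, lists and this rule were fixed before the data were examined, as were the alternatives, except where stated.

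The test was checked on counts simulated from the mean levels, library sizes and dispersions of the 10959 genes, with 100 of the better counted genes changed 2-fold and 100 changed 4-fold in 1 class. For high against low it recovered 60.0% of the 4-fold and 0% of the 2-fold changes. For very high against very low it recovered 60.0% and 5.00%, for very high against high 63.0% and 3.00%, and for very low against low 56.0% and 5.00%. False calls made up 3.17% to 5.80% of the calls. Under these settings changes of 2-fold were mostly missed. The simulation gave all classes the same dispersion for a gene and drew genes independently. In the data the replicates of the very low class lay much further apart than those of the very high class. The simulated shares therefore do not give the false calls or the recovery of the real comparisons.

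The alternatives were DESeq2 1.42.0 size factors or upper-quartile factors, no filter or a stricter one (1 CPM in at least 3 libraries), DESeq2 and limma-voom as tests, robust dispersions, the replicate number as a block, each library left out in turn, a fit of the 2 classes alone, and classes scored by their labelled bounds. A smooth muscle score, or smooth muscle and epithelial scores, as covariates, thinning to equal depth, and a fit of the very low and low classes alone without very low replicate 1 were added after seeing the data. No sample and no column was left out of the main test.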

Results

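The data describe the endometrium, the lining of the uterus, of grazing dairy cows (Bos taurus) on day 4 of the estrous cycle, early in diestrus, when the corpus luteum forms and blood progesterone rises. Endometrial biopsies were grouped by the progesterone concentration recorded for that day, and polyadenylated RNA was sequenced. There were 12 libraries in 4 classes of 3. The very low class lay below 0.25 ng/ml, the high class above 2.5 ng/ml and the very high class above 20 ng/ml. The low class lay below 1.4, which its labels give in mg/dl where the others give ng/ml, so the main trend used only the order of the classes. The series asked how progesterone in early diestrus is associated with gene expression in the endometrium. The labels do not say whether the 3 replicates of a class are 3 cows, so p-values measure the spread between these samples. The sample titles call the very low class ANE and the very high class SO, which the sources used here do not explain, and they do not say whether these classes differ from the others in more than progesterone.

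The libraries held 3772564 to 8379489 counted reads over 13930 gene symbols, and the smallest was very low replicate 2. Of these symbols, 10959 had enough counts to be tested. Replicates of the high class agreed closely (Spearman correlation 0.957 to 0.972 over genes), as did those of the very high class (0.961 to 0.976). Those of the low class (0.881 to 0.942) and above all of the very low class (0.738 to 0.877) lay further apart. Each of the 12 pairs of replicates within a class differed by more than counting noise (chi-square per degree of freedom 21.8 to 284), so none of these pairs is 1 library counted again. On the first principal component of log2 CPM (counts scaled to library size), which carried 35.7% of the variance, the 3 low libraries and very low replicates 2 and 3 lay between -108 and -24.9, and the 6 high and very high libraries lay between 16.7 and 51.0 together with very low replicate 1 (48.2). The second component, with 25.9%, set very low replicate 1 apart at -113.

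Tissue make-up differed between the libraries, and it did so along the class labels. The 14 tested smooth muscle markers, fixed as a list before the data were examined, had a mean log2 CPM of 8.44 to 9.70 in the 6 high and very high libraries. The mean was 4.19 to 5.19 in the 3 low libraries and 4.19 and 5.48 in very low replicates 2 and 3, whereas very low replicate 1 stood at 10.9. As examples chosen after their values were seen, the smooth muscle myosin heavy chain MYH11 had 1.92 to 3.12 CPM in the 5 libraries with low scores, 221 to 769 CPM in the 6 high and very high libraries and 1455 CPM in very low replicate 1. The smooth muscle actin ACTA2 ranged from 109 to 406 CPM in the former 5, from 4325 to 11312 CPM in the latter 6, and reached 26594 CPM in very low replicate 1. That same library had the lowest epithelial marker score, 3.49 against 5.86 to 7.98 in the other 11 libraries.

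**Figure D1:**
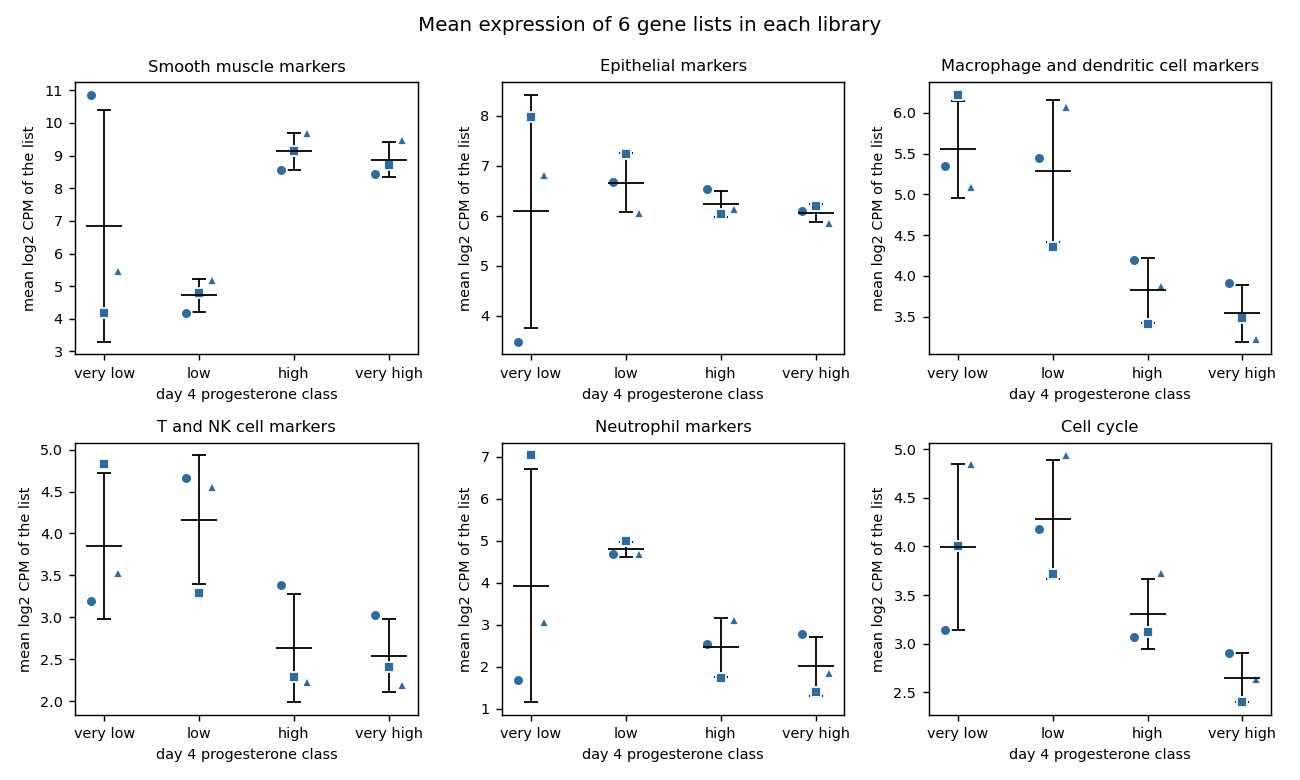
Mean log2 CPM of the tested members of 6 gene lists (vertical axes) in each of the 12 libraries, by day 4 progesterone class (horizontal axes); the circle, square and triangle are replicates 1, 2 and 3, the line is the mean of 3 and the bars are 1 SD. Smooth muscle scores lie at 8.44 to 9.70 in the high and very high libraries and at 4.19 to 5.48 in the low libraries and in very low replicates 2 and 3, while very low replicate 1 (circle) has 10.9 for smooth muscle and 3.49 for epithelium.

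The comparison of the extreme classes, very high against very low, gave 167 genes past an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 122 higher and 45 lower in the very high class. The largest rise was in PENK, which encodes proenkephalin, the precursor of the enkephalin opioid peptides. It went from 2.69 ± 3.31 CPM (SD, n = 3) in the very low class to 3208 ± 1813 CPM (SD, n = 3) in the very high class, a log2 fold change of 10.13 with a standard error of 1.19 (edgeR adjusted p = 0.0269). MEP1B, the beta subunit of the membrane metalloprotease meprin, rose from 0.519 ± 0.520 to 348.8 ± 249 CPM, by 9.24 ± 1.11 (SE) on the log2 scale (edgeR adjusted p = 0.0269). The other strongest rises were those of the carboxylesterase CES4A (7.98), the cell adhesion molecule NRCAM (7.74), the fatty acid transport protein SLC27A6 (6.89) and the cardiac actin ACTC1 (6.67), all in log2 units. Their edgeR adjusted p lay between 0.0309 and 0.0420. ACTC1 shares most of its coding sequence with other actins, so its count is uncertain, although very low replicate 1, richest in ACTA2, had 0 ACTC1 reads. The oxytocin receptor OXTR fell from 144.3 ± 79.1 to 4.58 ± 2.11 CPM (n = 3 each), a log2 fold change of -4.98 with a standard error of 0.81 (edgeR adjusted p = 0.0333). The other strongest falls were those of the focal adhesion protein TNS4 (-6.59), the uroplakin UPK1B (-6.16), the surface protein mesothelin MSLN (-5.06), the mitotic spindle protein DLGAP5 (-3.47) and the myeloid receptor PILRA (-3.25), whose locus overlaps the tested gene ZCWPW1 (edgeR adjusted p of 0.0399 to 0.0458).

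The steroid receptors themselves moved less in this comparison. PGR, the progesterone receptor, had 55.5 ± 19.0 CPM in the very low and 24.2 ± 3.84 CPM in the very high class (log2 -1.20, SE 0.28), and its edgeR adjusted p of 0.0561 missed the threshold. ESR1, the estrogen receptor alpha, had 99.3 ± 55.5 and 33.5 ± 14.2 CPM (log2 -1.57, SE 0.59, edgeR adjusted p = 0.149). Of the 15 tested steroid receptors and partners, 1 rose: FKBP5, a co-chaperone of steroid receptors that steroids themselves induce, at 84.6 ± 14.0 against 266.2 ± 61.8 CPM (log2 1.65, edgeR adjusted p = 0.0365). Adjusted over the list alone, 2 members were higher and 2 lower. Of the 16 estrogen-associated genes 1 fell, OXTR, and adjusted over the list alone 4 were higher and 7 lower.

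Genes grouped as progesterone-associated in advance went both ways. Of 29 tested, PENK and MEP1B rose and none fell, and adjusted over the list alone 8 were higher and 5 lower. The list as a whole was placed above other genes by the camera test (adjusted p = 0.0389), but its median log2 fold change was -0.07 against a mean of 1.08, and the adjusted p was 0.774 with an estimated correlation. Leaving out any of 3 single libraries ended that call (camera adjusted p of 0.0552 to 0.351). In the prostaglandin and oxytocin pathway 2 of 18 members rose and 1, OXTR, fell. AKR1B1, which makes prostaglandin F2α in the bovine endometrium, rose from 106.0 ± 50.5 to 585.2 ± 104 CPM (log2 2.46). HPGD, which inactivates prostaglandins, rose from 32.0 ± 33.4 to 429.2 ± 69.9 CPM (log2 3.74, SE 0.76). Among 34 genes of the IGF and growth factor axis BMP4 rose (log2 2.16) and TGFB2 fell (-2.36). Among 26 transporters the glutamine carriers SLC38A7 and SLC1A5 moved apart, by 2.19 and -2.36. In 3 further lists 1 member each rose: the metalloproteinase inhibitor TIMP2 (1.83) of 41 extracellular matrix genes, the fatty acid synthesis enzyme ACACA (2.79) of 35 lipid genes and the signalling ligand WNT11 (3.51) of 31 implantation regulators. The edgeR adjusted p of the genes in this paragraph other than PENK and MEP1B lay between 0.0333 and 0.0476.

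**Figure D2:**
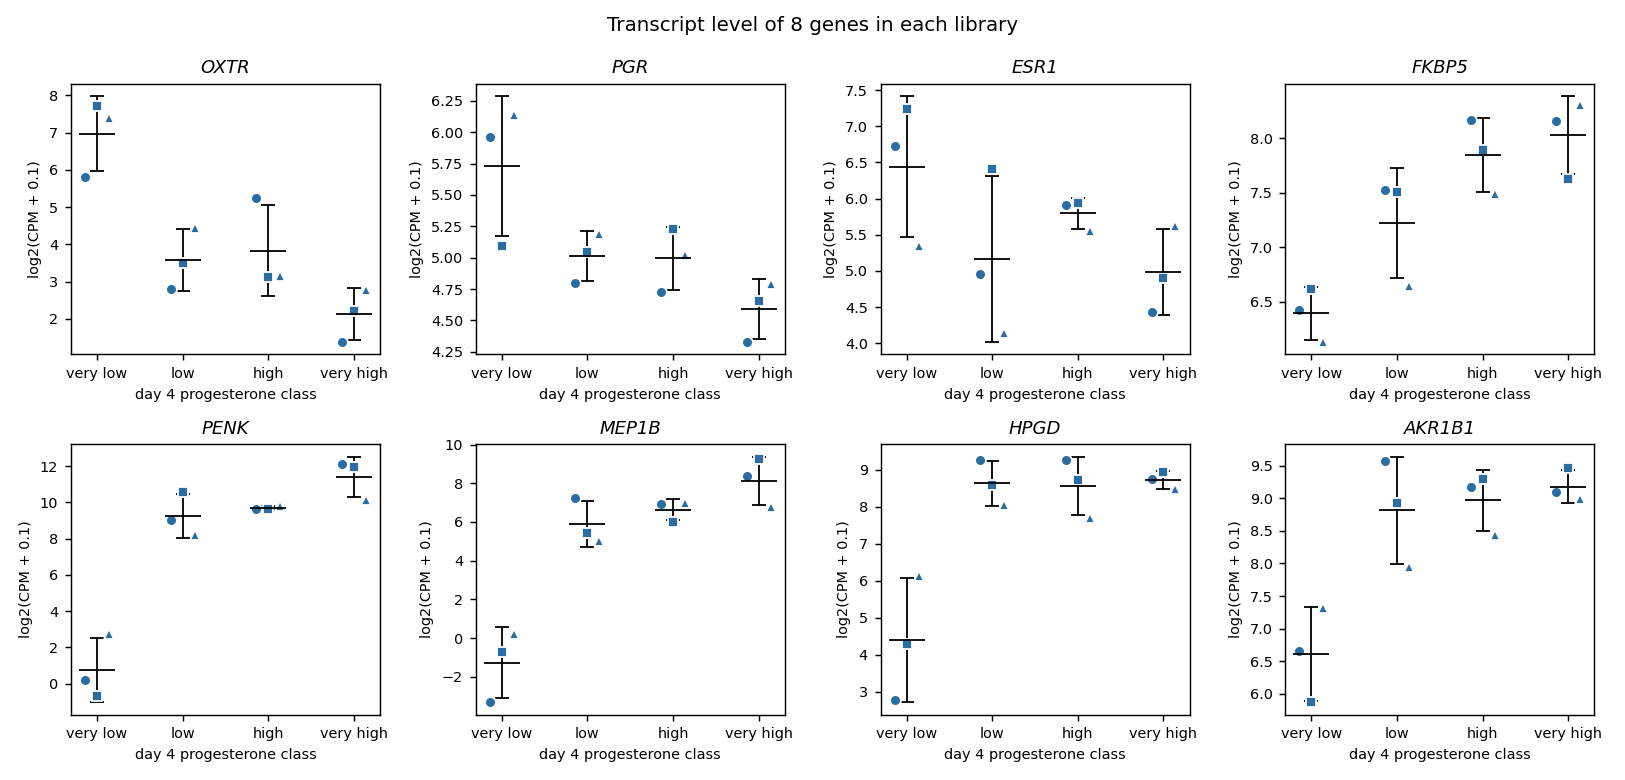
Transcript level of 8 genes named in the comparisons, as log2(CPM + 0.1) (vertical axes, each with its own range), in each of the 12 libraries by day 4 progesterone class; the circle, square and triangle are replicates 1, 2 and 3, the line is the mean of 3 and the bars are 1 SD. PENK, MEP1B, HPGD and AKR1B1 are lower in all 3 very low libraries than in the other 9, and OXTR is higher in all 3 (56.2 CPM or more) than in the other 9 (37.8 CPM or less).

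Several cell cycle and leukocyte lists were placed lower in the very high class by camera's preset correlation, and none with an estimated correlation. Of 37 cell cycle genes 3 fell, TPX2 (log2 -2.72), KIF11 (-3.17) and DLGAP5, all parts of the mitotic spindle machinery, and adjusted over the list alone 23 were lower and 1 higher (camera adjusted p = 2.65e-11; adjusted p = 0.774 with an estimated correlation). Both called members of the 13 macrophage and dendritic cell markers fell, CD68 from 83.0 ± 35.2 to 14.4 ± 3.64 CPM (log2 -2.52) and the integrin ITGAM (-2.61). The edgeR adjusted p of these 5 genes lay between 0.0333 and 0.0458. All 13 of these markers were lower when adjusted over the list alone (camera adjusted p = 2.65e-11; adjusted p = 0.681 with an estimated correlation). Of 20 T and NK cell markers CD8B fell (-1.27, edgeR adjusted p = 0.0482), and 9 were lower adjusted over the list alone (camera adjusted p = 5.23e-07; adjusted p = 0.774 with an estimated correlation). With smooth muscle and epithelial scores as covariates, a fit chosen after seeing the data, these 3 list calls were lost: the means went from -1.63 to -0.33 for cell cycle (camera adjusted p = 0.567), from -2.18 to -0.70 for macrophage (0.218) and from -1.54 to 0.45 for T and NK cell markers (0.511). In the same fit the progesterone-associated mean went from 1.08 to 2.34, the endothelial mean from 0.43 to 1.65 and the immediate early mean from -1.55 to -3.37. These 3 calls were kept (camera adjusted p of 0.00109 or less). Inflammation kept its call at -1.73. The neutrophil list lost it at -1.42. The inflammation list (median -3.13, camera adjusted p = 2.44e-06) and the neutrophil list (median -3.80, camera adjusted p = 0.0214) lay lower as well, both with an adjusted p of 0.861 with an estimated correlation, and in neither did a single gene pass. Very low replicate 2 carried both: without it the list means went from -2.87 to -0.57 for inflammation (camera adjusted p = 0.103) and from -3.80 to -0.58 for neutrophil markers (camera adjusted p = 0.608). The immediate early and heat shock list was lower (median -0.97) and the endothelial list higher (median 0.42), each at a camera adjusted p of 0.0453 and an adjusted p of 0.972 with an estimated correlation. Leaving out any of 3 single libraries ended the former call and any of 7 the latter. The endothelial mean went from 0.43 to 0.20 without very low replicate 1 (camera adjusted p = 0.403) and to 0.47 without high replicate 2 (camera adjusted p = 0.0564). The other lists did not pass: the median was -0.21 for interferon-stimulated genes, 0.48 for B and plasma cell, -1.31 for epithelial, -0.0023 for ciliated cell, -0.42 for stromal fibroblast and -0.36 for smooth muscle markers. The mean epithelial scores were nearly equal, 6.09 (SD 2.33) in the very low and 6.05 (SD 0.18) in the very high class. The very low libraries ran from 3.49 to 7.98 in that score. The lists of this paragraph moved beside smooth muscle scores of 8.44 to 9.47 in the very high libraries and of 10.9, 4.19 and 5.48 in the very low ones.

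Between the extreme classes 25.7% of tested genes had CPM ranges that did not overlap, where chance gives 10%, and 2609 genes had an unadjusted p under 0.05, where chance gives 548. The count of 167 depended on single libraries and on the fit. It was 643 without very low replicate 1, 324 without very low replicate 3, 1 without very low replicate 2, 0 without very high replicate 1 or 2, 2 without very high replicate 3, 341 without low replicate 3, and 74, 52 and 17 without high replicates 1, 2 and 3. It was 1510 with DESeq2, 1 with limma-voom, 1766 with the smooth muscle score as a covariate, 0 with smooth muscle and epithelial scores (both fits chosen after seeing the data), and 0 in an edgeR fit of these 6 libraries alone. In the fits without very high replicates 1 and 2 and of 6 libraries the genes with an unadjusted p under 0.05 numbered 2024, 1738 and 1823. The calls of the named genes held in 6 (CD8B), 9 (CES4A), 10 (DLGAP5) and up to 18 (PENK) of 24 alternatives, in 11 of 23 for TNS4, and all kept their direction.

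The trend over the 4 ordered classes called 820 genes (edgeR adjusted p under 0.05), 331 with a rising and 489 with a falling slope. CHGA, which encodes the secretory granule protein chromogranin A, climbed from 2.41 ± 1.65 CPM in the very low class through 7.61 ± 4.96 and 39.9 ± 22.0 to 94.3 ± 37.4 CPM in the very high class (SD, n = 3 each), a slope of 1.82 ± 0.21 (SE) log2 units per class (edgeR adjusted p = 0.0119). The glutamate receptor GRM7 (2.07 per class), the adenylyl cyclase ADCY8 (1.71), ZSWIM7 (0.58), the lysine methyltransferase EEF1AKMT1 (0.40) and the mitochondrial dehydrogenase DHTKD1 (0.39) also rose. The slopes fell for ITGAM (-0.90), the alpha tubulin TUBA4A (-0.87), SLC1A5 (-0.87), VSTM2L (-0.67), GNPTAB (-0.46), which tags enzymes for the lysosome, and ARMCX3 (-0.39). The edgeR adjusted p of these genes other than CHGA was 0.0208. The receptors of the pairwise comparisons were looked up here after their values were seen. OXTR fell by 1.52 and PGR by 0.37 log2 units per class and FKBP5 rose by 0.56 (edgeR adjusted p = 0.0216, 0.0341 and 0.0216), while ESR1 had a slope of -0.45 (edgeR adjusted p = 0.131). The falls were not even steps. From the very low to the very high class OXTR had 144.3, 13.2, 18.4 and 4.58 CPM and PGR 55.5, 32.3, 32.1 and 24.2 CPM. FKBP5 rose at each step (84.6, 155.1, 234.2 and 266.2 CPM).

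Among macrophage and dendritic cell markers 11 of 13 fell (camera adjusted p = 2.86e-12; adjusted p = 0.423 with an estimated correlation), and this was the 1 list past the threshold in fry, a test of whether a list's genes move one way on balance (adjusted p = 0.0239). Of cell cycle genes 14 of 37 fell and none rose (camera adjusted p = 2.86e-12). Of inflammation genes 10 of 42 (camera adjusted p = 1.76e-08), of T and NK cell markers 3 of 20 (1.76e-08) and of neutrophil markers 2 of 8 (0.00534) fell and none rose. For these 4 lists the adjusted p was 0.758 with an estimated correlation, and the neutrophil call was lost without very low replicate 2 (camera adjusted p = 0.113). The T and NK cell call (mean slope -0.64 to -0.18, camera adjusted p = 0.160) and the neutrophil call (-1.40 to -0.29, camera adjusted p = 0.401) were lost with smooth muscle and epithelial scores as covariates. In that fit the other 3 passed with smaller slopes, -0.61 to -0.31 for cell cycle, -1.07 to -0.44 for inflammation and -0.83 to -0.51 for macrophage markers. Endothelial markers kept their call there (0.24) and smooth muscle markers lost it (0.011), the latter by construction. Smooth muscle (median 0.02 per class, camera adjusted p = 0.0282) and endothelial markers (median 0.14, camera adjusted p = 0.0493) were placed above other genes. In neither did a member pass, and the adjusted p was 0.873 with an estimated correlation. Leaving out any of 6 and 8 single libraries ended these calls. In those fits the smooth muscle mean slope of 0.0052 ran from -0.10 without very low replicate 3 to 0.012 without high replicate 2. The endothelial mean went from 0.14 to 0.056 without very low replicate 1. Of the estrogen-associated genes 6 of 16 fell and 1 rose, and the list did not pass (camera adjusted p = 0.292). The slopes run alongside the smooth muscle scores, which are high in the upper 2 classes and in very low replicate 1. With classes scored by the log2 of their labelled bounds no gene passed in edgeR (2688 with an unadjusted p under 0.05), and CHGA had an edgeR adjusted p of 0.0516. That score read the bound of the low class as if in ng/ml and mixed upper with lower bounds. On the class ranks 2008 genes passed in DESeq2 and 360 in limma-voom. Without very high replicate 3 the count was 1, without very high replicate 2 it was 36, without very high replicate 1 194, without very low replicates 1, 2 and 3 1462, 119 and 532, and without high replicates 1, 2 and 3 236, 279 and 278.

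In the comparison of the middle classes, high against low, no gene passed an adjusted p of 0.05 (edgeR), while DESeq2 called 241 and limma-voom 0. In edgeR 1125 had an unadjusted p under 0.05 where chance gives 548, and 20.0% of genes did not overlap where chance gives 10%. The genes with the smallest p were named all the same. The atrial myosin light chain MYL4 had 26.7 ± 20.1 against 0.851 ± 0.418 CPM (log2 4.94, SE 0.78), and its locus overlaps the tested gene CDC27. The epithelial envelope protein EVPL had 71.0 ± 4.90 against 12.2 ± 2.37 CPM (log2 2.54, SE 0.40). ACTC1 stood at 37.5 ± 10.2 against 0.433 ± 0.511 CPM, ADCY8 at 35.5 ± 13.0 against 4.37 ± 2.09 CPM, and the ATP-gated channel P2RX1, of smooth muscle and platelets, at 8.63 ± 5.08 against 0.174 ± 0.202 CPM. Very low replicate 1, with a smooth muscle score of 10.9, had only 4 P2RX1 and 9 MYL4 reads. The high libraries had 34 to 105 and 90 to 364. Lower in the high class were the macrophage marker CD68 (25.9 ± 3.80 against 85.5 ± 43.2 CPM), GAPT, PKIB and CRIP1 (log2 -1.72, -2.69, -1.81 and -1.28), 4 of the 5 genes that the rule takes. The edgeR adjusted p of these 9 genes lay between 0.310 and 0.351. PGR, ESR1 and OXTR had log2 fold changes of -0.01 ± 0.27, 0.33 ± 0.58 and 0.47 ± 0.69 (SE; edgeR adjusted p = 0.994, 0.874 and 0.848), and the sign of each changed when single libraries were left out.

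Of the 22 gene lists, 9 passed camera's preset correlation between high and low, and none passed with an estimated correlation. Smooth muscle markers were higher (median log2 4.20; 14 of 14 positive, 13 of them past the threshold when adjusted over the list alone; camera adjusted p = 1.23e-16; adjusted p = 0.282 with an estimated correlation). The 8 others were lower. They were T and NK cell (median -1.65), B and plasma cell (-1.83), macrophage and dendritic cell (-1.83) and neutrophil markers (-2.49), with camera adjusted p of 4.39e-13, 4.37e-06, 5.19e-12 and 4.48e-05, and each of these had an adjusted p of 0.282 with an estimated correlation. Adjusted over the list alone, 7 of 20 T and NK, 0 of 9 B and plasma cell, 9 of 13 macrophage and 1 of 8 neutrophil markers were lower. Inflammation (median -1.54; 39 of 42 negative), cell cycle (-1.25; 33 of 37 negative), interferon-stimulated (-0.46; 25 of 28 negative) and ciliated cell genes (-1.55; 20 of 21 negative) had adjusted p of 0.306, 0.363, 0.624 and 0.624 with an estimated correlation. The 8 lower lists stood beside smooth muscle scores of 8.55 to 9.70 in the high libraries and 4.19 to 5.19 in the low ones. With the smooth muscle score as a covariate, a fit chosen after seeing the data, 5 lists passed, of which 1 was among the 9, and the mean changes of the interferon-stimulated and ciliated cell lists turned to 0.50 and 1.08. In both covariate fits the smooth muscle scores of the 2 classes do not overlap, so the adjusted differences are extrapolations. With smooth muscle and epithelial scores as covariates, also chosen after seeing the data, 4 of the 8 lower lists changed direction. They were T and NK cell (mean 2.17, camera adjusted p = 0.000163), cell cycle (1.30, camera adjusted p = 0.00171), B and plasma cell (2.16, camera adjusted p = 0.134) and macrophage markers (1.32, camera adjusted p = 0.0670). In that fit ciliated cell markers came to -3.20 and inflammation genes to -1.65 with the call kept (camera adjusted p = 5.62e-12 and 0.00171). The interferon-stimulated (-0.44) and neutrophil calls (-0.74) were lost. The smooth muscle call (0.15) was lost by construction, since the score of that list is a covariate. Without low replicate 2 the mean of the ciliated cell list went from -1.35 to -0.58 (camera adjusted p = 0.444). Without very low replicate 1, whose spread enters the shared fit, 76 genes passed, and 26 passed in a fit of these 6 libraries alone.

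**Figure D3:**
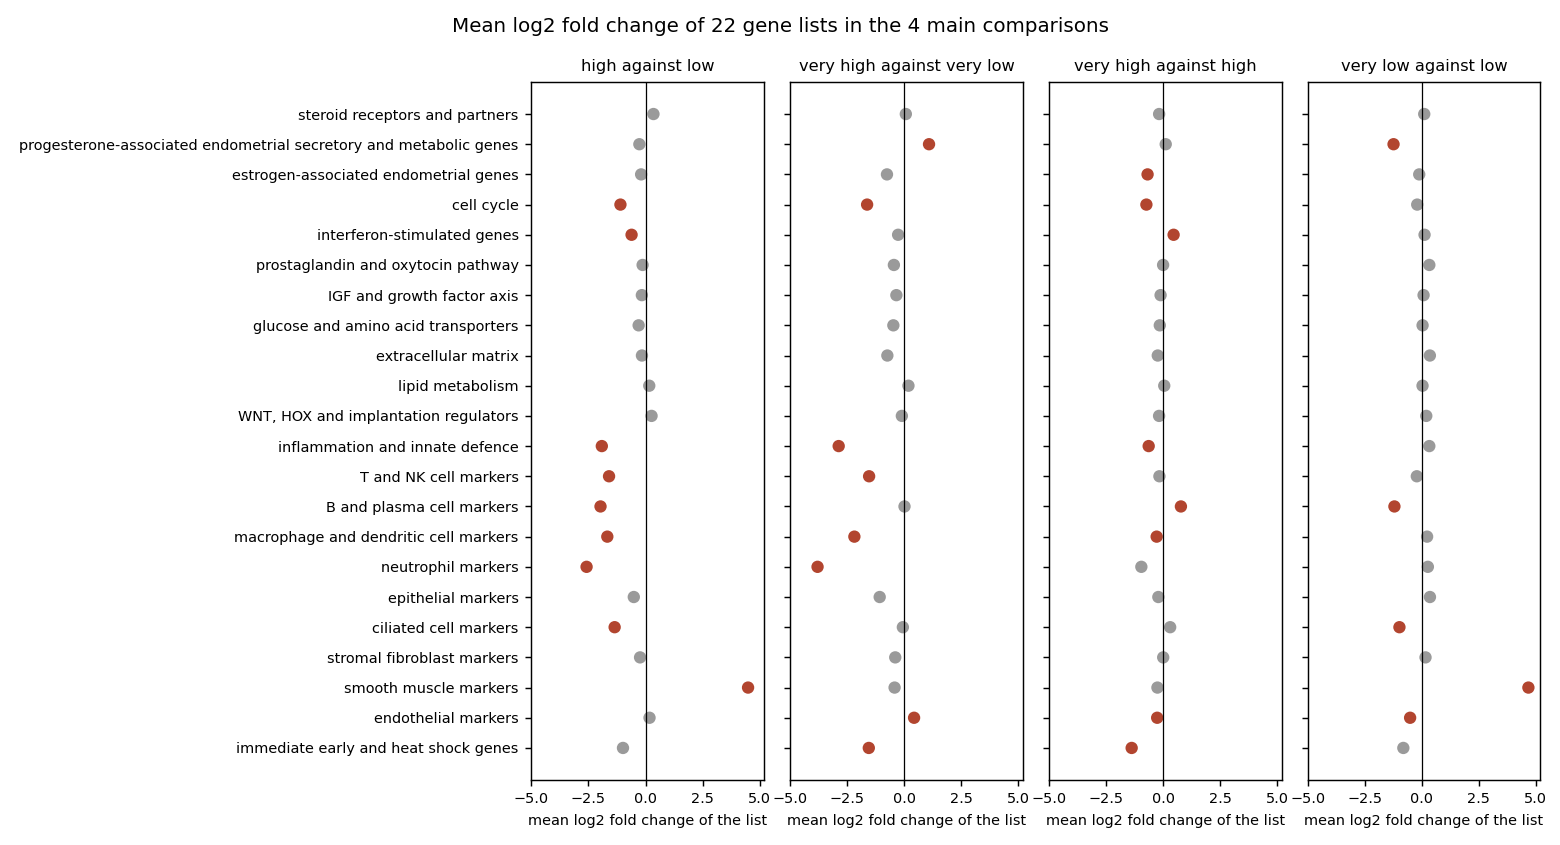
Mean log2 fold change of the tested members of 22 gene lists (horizontal axes) in the 4 main comparisons; red marks lists past a camera adjusted p of 0.05 with the preset correlation of 0.01 and grey the others. With an estimated correlation no list passed in any of the 4 comparisons.

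At the lower end, very low against low, no gene passed in edgeR, while DESeq2 called 293 and limma-voom 0. In edgeR 1269 had an unadjusted p under 0.05 where chance gives 548, and 9.74% of genes did not overlap where chance gives 10%. PENK had 2.69 ± 3.31 CPM in the very low and 771.5 ± 650 CPM in the low class (log2 -8.07, SE 1.11), and MEP1B had 0.519 ± 0.520 and 76.1 ± 66.5 CPM (-7.05, SE 1.04). The Krüppel-like factor KLF15 had 8.26 ± 2.77 and 33.6 ± 10.9 CPM (-2.03, SE 0.30), the flavin monooxygenase FMO2 1.05 ± 0.784 and 16.9 ± 4.56 CPM (-3.96, SE 0.61), and the phosphatase inhibitor PPP1R1B 9.28 ± 4.80 and 52.1 ± 21.8 CPM (-2.47, SE 0.42). Their edgeR adjusted p lay between 0.130 and 0.218. Higher in the very low class were OXTR (144.3 ± 79.1 against 13.2 ± 7.65 CPM; log2 3.45, SE 0.74, edgeR adjusted p = 0.275), CLIP2 (1.27), TMEM98 (0.90), the stress granule protein G3BP1 (0.72), CALU (1.46) and the potassium channel KCNS3 (2.75), with edgeR adjusted p of 0.218 to 0.275. PGR (0.78, edgeR adjusted p = 0.346) and ESR1 (1.16, edgeR adjusted p = 0.474) did not pass.

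Among the lists, 5 passed with the preset correlation. Progesterone-associated genes were lower (median -0.24, mean -1.24; 7 of 29 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000427; adjusted p = 0.530 with an estimated correlation). Ciliated cell (median -1.03), B and plasma cell (-1.19) and endothelial markers (-0.59) were lower and smooth muscle markers (4.52) higher, with camera adjusted p of 0.000995, 0.00285, 0.0032 and 1.02e-05 and an adjusted p of 0.975 with an estimated correlation in each. Very low replicate 1, with its smooth muscle score of 10.9 and epithelial score of 3.49, weighed on these list calls: without it 1 list passed, which was none of the 5. The list means went from 4.67 to 0.27 for smooth muscle, from -1.24 to -1.01 for progesterone-associated genes, from -0.98 to -0.60 for ciliated cell, from -1.20 to -0.82 for B and plasma cell and from -0.51 to -0.29 for endothelial markers, with camera adjusted p of 0.0751 to 0.655. Low libraries weighed on them too: without low replicate 2 the ciliated cell mean was -0.24 (camera adjusted p = 0.451), and without low replicate 3 the endothelial mean was -0.14 (0.387) and the B and plasma cell mean -0.73 (0.158). The B and plasma cell and endothelial means turned to 0.29 and 0.24 with smooth muscle and epithelial scores as covariates. In that fit the ciliated cell mean grew to -1.76 and the progesterone-associated list kept its call at -0.89 (camera adjusted p = 8.43e-18 and 0.0230). The smooth muscle list lost its call there by construction. All 3 very low libraries lay below all 3 low ones in the progesterone-associated score (2.76 to 4.56 against 5.36 to 5.52). Chance separates 3 from 3 libraries in 1 direction or the other in 10% of cases, and 9.74% of tested genes were separated here. The separation of the score is therefore weak evidence. Without very low replicate 2, 12 lists passed. Without low replicate 3, 13 genes passed, and without very low replicate 3, 16.

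At the upper end, very high against high, no gene passed (edgeR; 87 with an unadjusted p under 0.05 where chance gives 548; DESeq2 and limma-voom called 0), and 7.09% of genes did not overlap where chance gives 10%. The genes with the smallest p were the transcription factor ETV5 (25.0 ± 4.30 against 9.08 ± 3.29 CPM; log2 1.46, SE 0.37), REEP5 (0.76), MAP4K2 (1.07), PNPLA4 (1.43) and the linker histone HIST1H1C (1.14), higher in the very high class, and CD8B (7.39 ± 0.804 against 17.0 ± 3.58 CPM; -1.20, SE 0.27), SERPINA1 (-3.50), CBX3 (-0.74), the fructose transporter SLC2A5 (-4.37) and CENPF (-2.31), lower. Each had an edgeR adjusted p of 1, as had OXTR (-2.01, SE 0.73), ESR1 (-0.74) and PGR (-0.41). HIST1H1C belongs to a family of near-identical genes and its count is uncertain. Smooth muscle scores were alike in range here, 8.44 to 9.47 against 8.55 to 9.70. Of the lists, 8 passed with the preset correlation. Cell cycle (median -0.57), estrogen-associated (-0.39), immediate early and heat shock (-0.90), inflammation (-0.27), macrophage (-0.24) and endothelial genes (-0.25) were lower, and interferon-stimulated genes (0.44) and B and plasma cell markers (1.11) higher. Their camera adjusted p ran from 1.25e-17 for cell cycle to 0.0104 for macrophage markers, and with an estimated correlation the adjusted p was 0.318 for the estrogen-associated list and 0.497 to 0.878 for the others. Without high replicate 1 the mean of the immediate early and heat shock list went from -1.37 to -0.051 (camera adjusted p = 0.712) and that of the macrophage list from -0.28 to -0.036 (camera adjusted p = 0.475). Without high replicate 3 the mean of the inflammation list turned to 0.18, and without very high replicate 3, 4 lists passed and camera's direction for the endothelial list turned (mean -0.016). The B and plasma cell mean went from 0.78 to 0.48 without high replicate 3 (camera adjusted p = 0.0826) and to 0.27 without very high replicate 3 (0.168), and the interferon-stimulated mean from 0.46 to 0.27 without high replicate 2 (0.0564). The inflammation, B and plasma cell and immediate early calls were lost with smooth muscle and epithelial scores as covariates (means -0.39, 0.51 and -0.51). The other 5 calls were kept there, with larger means for macrophage (-0.69), endothelial (-0.54), cell cycle (-1.06) and interferon-stimulated genes (0.53) and a smaller one for estrogen-associated genes (-0.44).

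The pairs of classes outside the 4 main comparisons were run for gene counts and gene lists only. Very high against low gave no gene (edgeR; 1304 with an unadjusted p under 0.05; DESeq2 370, limma-voom 0) and 11 lists with the preset correlation, none with an estimated correlation (smallest adjusted p = 0.203). Cell cycle genes had a median of -1.97 there, with 26 of 37 lower adjusted over the list alone. Tissue markers differed beside them: smooth muscle scores were 8.44 to 9.47 in the very high and 4.19 to 5.19 in the low libraries. Macrophage scores were 3.23 to 3.91 and 4.35 to 6.07. Very low against high gave no gene (edgeR; 2058 with an unadjusted p under 0.05; DESeq2 788, limma-voom 0) and 10 lists, none with an estimated correlation (smallest adjusted p = 0.734). Macrophage markers had a median of 1.91 in the very low class, with 13 of 13 higher adjusted over the list alone, but the smooth muscle, implantation regulator and progesterone-associated lists had medians of 0.20, 0.11 and 0.12 where camera placed them lower. The joint test of the 4 classes called no gene (edgeR; 1954 with an unadjusted p under 0.05; DESeq2 1303, limma-voom 0). Its 6 smallest p belonged to ACTC1, PENK, ADCY8, MEP1B, CHGA and KLF15, each with an edgeR adjusted p of 0.0856.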

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

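The covariate fits, the thinning to equal depth and the fit of the very low and low classes alone without very low replicate 1 were chosen after seeing the data. Of 2070 alternative values for 86 gene results, 1673 kept direction and side of the threshold, 327 fell below it, 54 passed it anew and 16 changed direction. Of 930 for 37 list results these numbers were 738, 179, 0 and 13, and in 3 of the 13 camera's direction turned while the mean kept its sign. Only a result past the threshold in the main test could fall below it. All 37 list results had passed but only a part of the 86 gene results, so 327 is not to be read as a share of 2070. For very high against very low the named calls held in 6 (CD8B) to 18 (PENK) of 24 alternatives. The 167 genes for very high against very low, the 820 of the trend and the 0 of the other tests stayed within 1.5 times under DESeq2 size factors (181 and 784), upper-quartile factors (162 and 863), no filter (175 and 700), a stricter filter (192 and 770) and robust dispersions (161 and 792). The alternatives planned for normalized values, a pseudocount and a filter on low values, were not run because the values are counts. The depth of 3772564 counts in very low replicate 2 limits weakly expressed genes most. Where a value below departs from these, the cause was not tested unless stated.

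With the DESeq2 test the calls were 241 for high against low, 1510 for very high against very low, 293 for very low against low, 370 for very high against low, 788 for very low against high, 1303 in the joint test and 2008 for the trend, and 0 for very high against high. With limma-voom they were 1 for very high against very low, 360 for the trend and 0 elsewhere, and 5 lists instead of 8 passed for very high against very low. With an estimated correlation camera called 0 lists for high against low, very high against very low, very high against high, very low against low and the trend. In fry the numbers were 0, 0, 0, 0 and 1. With classes scored by their labelled bounds the trend called 0 genes. In fits of 2 classes alone the calls were 26 for high against low, 0 for very high against very low and 87 for very high against low, where fewer libraries share the spread. The fit of the low libraries with very low replicates 2 and 3 alone called 0 genes (373 with an unadjusted p under 0.05) and 2 lists.

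With the replicate number as a replicate block, very high against very low called 0 genes and 5 lists and the trend 180 genes. The numbers pair nothing in the data: over 18 pairs of libraries with the same number the correlation of deviations from the class mean was -0.298 to 0.294, and 4 of 12 libraries correlated best with one of their own number.

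With the smooth muscle score as a covariate the calls were 38 for high against low, 1766 for very high against very low, 93 for very high against low, 1102 for very low against high, 410 in the joint test and 1532 for the trend, with 5 lists for high against low and 2 for very low against low. The mean log2 fold change for high against low turned to 0.50 for interferon-stimulated genes and 1.08 for ciliated cell markers. Smooth muscle markers came to 0.029 there and 0.027 for very low against low, with camera's direction turned, by construction. With smooth muscle and epithelial scores as covariates the calls were 0 for very high against very low and 354 for the trend, with 5 lists for very high against very low and 8 for very low against low. For high against low, where the smooth muscle scores of the classes do not overlap and the fit extrapolates, ESR1 came to -3.73, CD68 to 0.54 and CRIP1 to 0.43. The list means there came to 1.30 for cell cycle, 2.17 for T and NK, 2.16 for B and plasma and 1.32 for macrophage markers (camera adjusted p = 0.00171, 0.000163, 0.134 and 0.0670). For very low against low ESR1 came to -0.14, B and plasma cell markers to 0.29 and endothelial markers to 0.24, and for very high against very low T and NK cell markers came to 0.45. After thinning to equal depth the trend called 546 genes, with fewer reads, and very high against very low 185.

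Leaving out 1 library at a time gave 0 to 76 genes for high against low, 0 to 643 for very high against very low, 0 to 0 for very high against high, 0 to 16 for very low against low, 0 to 65 for very high against low, 0 to 130 for very low against high, 0 to 219 in the joint test and 1 to 1462 for the trend. The highest value came without very low replicate 1 in 6 of these 8 and without very low replicate 3 for very low against low. The numbers of lists were 9 to 15 for high against low, 6 to 10 for very high against very low, 4 to 12 for very high against high, 1 to 12 for very low against low and 5 to 10 for the trend. The log2 fold change of PGR for high against low, -0.011, lay near 0 throughout. It was 0.0082 with no filter, 0.0045 with a stricter one, 0.25 after thinning, 0.012 and 0.081 without low replicates 2 and 3, 0.0044 without very low replicate 2, 0.13 without high replicate 1, and 0.0058, 0.0060 and 0.0057 without very high replicates 1, 2 and 3. ESR1 ranged from -0.045 without low replicate 3 to 1.22 without low replicate 2, and OXTR from -0.60 without high replicate 1 to 1.03 without low replicate 3. For very high against high the mean of the inflammation list ranged from -1.35 without very high replicate 1 to 0.18 without high replicate 3. That of the endothelial list ranged from -0.40 without high replicate 3 to -0.016 without very high replicate 3, where camera placed it above other genes.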

Other observations

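The genes in the first 2 paragraphs were chosen after their values were seen, and so were the tests of progesterone class and of dilution. Transcripts of innate defence differed most within the very low class. Very low replicate 2 had the highest neutrophil score (7.03 against 1.40 to 5.0 in the other 11 libraries) and inflammation score (7.74 against 3.24 to 6.25). In that library the calcium-binding proteins S100A12, S100A8 and S100A9 reached 2262, 502 and 512 CPM, the iron-binding lactoferrin LTF 15745 CPM, the immunoglobulin receptor PIGR 5164 CPM, and the chemokine receptors CXCR1 and CXCR2 91.9 and 67.1 CPM. It had the highest score of interferon-stimulated genes as well (6.40), with MX2 at 151 CPM. Very low replicate 1 had 8.84 CPM of the acute phase gene SAA3 and 4.60 CPM of the tracheal antimicrobial peptide TAP, and low replicate 1 had 10629 and 2857 CPM. Gastrin-releasing peptide, GRP, ran from 139 CPM in very low replicate 1 to 18716 CPM in low replicate 1.

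Immediate early genes differed between libraries of the same class. Their score was 9.0 in low replicate 2, 7.82 in high replicate 1, 7.50 and 7.21 in very low replicates 2 and 3 and 5.35 to 6.17 in the other 8 libraries. In low replicate 2, high replicate 1 and very low replicate 3, FOS had 3379, 794 and 756 CPM, FOSB 1746, 262 and 124 CPM, and EGR1 1693, 358 and 305 CPM. Very high libraries had 9.76 to 28.2 CPM of FOS. Among other progesterone-associated genes, TDGF1 had 4.07 and 4.13 CPM in very low replicates 1 and 2, 271 CPM in very low replicate 3 and 411 to 3970 CPM in the other 9 libraries. The growth factor binding protein gene IGFBP1 had 0.18 to 0.65 CPM in the very low class and 7.85 to 30.1 CPM in the very high class. The cilia regulator FOXJ1 was at 0 CPM in very low replicate 1 and at 135 CPM in low replicate 2, and KRT7 at 757.6 CPM in very low replicate 2 and 19.4 to 33.5 CPM in the very high class.

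Smooth muscle markers were higher in the high than in the low libraries. Thinning every library to equal depth left their mean log2 fold change at 4.46. Such thinning keeps a gene's expected share of the reads, so this value does not decide on library depth. Total counts were 6952815 to 7487867 in the high and 7036929 to 8096116 in the low libraries, so depth did not separate these classes. A second list of 25 smooth muscle genes, fixed before it was looked up, had a median log2 fold change of 2.11 with 25 of 25 positive, as smooth muscle tissue in the biopsies would give. Whether that tissue goes with the progesterone class of the cow or with how deep a biopsy reached stays open: 2 of the 3 very low libraries lay above every low library, 1 of them (5.48 against 5.19) by little, and sampling depth is not given in the sources used here.

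The 167 genes that changed between very high and very low could reflect the smooth muscle and epithelial content of the biopsies or the lower depth of 1 very low library. With both content scores as covariates the log2 fold changes of these genes kept a median ratio of 1.05 (quartiles 0.837 and 1.26) to those without. In that fit 167 of 167 kept their sign. The genes were called in the same data, where the very low libraries differ widely in content (smooth muscle 4.19 to 10.9, epithelial 3.49 to 7.98). Genes that follow content could hardly be among them, so the ratio does not decide on content. The calls themselves were lost in the fit with both covariates, where the median standard error rose from 0.408 to 0.708. In that fit 77.2% of the genes had a ratio of at least 0.8, so part of them also had smaller fold changes. After thinning, the ratio was 1.01 over 164 genes still tested (quartiles 0.976 and 1.04). Random thinning keeps a gene's expected share of the reads, and the smallest library set the target. The ratio therefore does not decide on depth. A difference that comes with the progesterone class, or with any other trait of these 6 samples, remains open as a hypothesis beside content and depth.

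Immune cell lists were lower in the high than in the low libraries. If smooth muscle only diluted the endometrium, immune scores would move like epithelial, stromal and endothelial ones, but the immune minus non-immune score was lower by 1.76 (difference -1.76, SE 0.44; exact permutation p = 0.1, the smallest possible). Against the epithelial score alone the difference was -1.41 (SE 0.72), and muscle has stromal and endothelial cells of its own, so dilution stays open. With smooth muscle and epithelial scores as covariates, in a fit where the smooth muscle score separates the 2 classes, the T and NK, B and plasma and macrophage lists turned to 2.17, 2.16 and 1.32 and the neutrophil list came to -0.74. The progesterone class of the cow stays open too: the score was -1.79 (SD 1.39) in the very low class, -1.62 (SD 0.65) in the low, -3.39 (SD 0.41) in the high and -3.22 (SD 0.42) in the very high class, and the 3 very low libraries spread from -3.06 to -0.306.

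Other splits of the same samples were counted for each test. With 6 libraries there are 10 splits of 3 against 3, so the smallest share is 0.1 and chance cannot be excluded at 0.05. For very high against very low 1 of 10 splits, the real one, gave as many as 167 genes, and the highest of the others gave 0. For high against low, very high against high, very low against low, very high against low and very low against high, where no gene was called, 10 of 10 splits gave as many in each. In very low against low 1 other split gave 1027 genes, with low replicates 1 and 2 and very low replicate 2 on one side. For the joint test 60 of 60 splits gave as many as the 0 called, the highest 2. Where no gene is called, every split must give as many. These shares therefore decide nothing for the joint test or for the pairs without a called gene. For the trend 1 of 60, the real one, gave as many as 820 and the highest of the others gave 1. If the 12 libraries are independent, this argues against a chance order of them. The labels do not say whether they come from different cows. The order also runs alongside the smooth muscle scores, so the splits do not tell progesterone from tissue content. Without very high replicate 3 the trend called 1 gene.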
